A study of Mus musculus with 2 samples.

How the data were processed

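The data were single-cell RNA counts of live CD45+ cells sorted by flow cytometry from subcutaneous tumours of mice, with 7AAD to exclude dead cells. There was 1 library from wild-type (WT) C57BL/6J mice and 1 from CD94-deficient (CD94-KO) mice of the same strain. Libraries were made with droplet-based 3′ chemistry from 10x Genomics and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. They were made with Cell Ranger 5.0.0, per the file headers, and barcodes not called as cells had already been removed, per the labels' protocols. The mm10 genome build and Seurat 4.0 are named in the submitters' processing notes, with no role given for Seurat. The annotation release behind the counts was not given in the sources used here. Each library's table had 27998 genes. T cell receptor and immunoglobulin gene segments were not used here.

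The WT library held 5358 barcodes with 40261366 UMIs and a median of 2820.5 UMIs per barcode. The CD94-KO library held 5175 barcodes with 46107433 UMIs and a median of 7244. Barcodes were kept with at least 500 UMIs, at least 300 genes and under 10% mitochondrial UMIs. The mitochondrial limit failed 777 WT and 408 CD94-KO barcodes and the gene minimum 31 and 26, some of them the same barcodes, which left 4571 and 4765. Doublets were scored per library with Scrublet as supplied in scanpy. Its automatic threshold marked 1 WT cell (0.022%) and 0 CD94-KO cells, which meant that it had not worked, so the 4% of cells with the highest scores were removed, 183 WT and 191 CD94-KO cells. The kept 4388 WT cells had a median of 4768.5 UMIs and 1651 genes, and the kept 4574 CD94-KO cells had 7799 UMIs and 2194 genes. Of the kept cells, 29.9% in the WT library and 7.08% in the CD94-KO library had under 1000 UMIs.

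Both libraries were clustered together without batch correction, since a correction between a pair of libraries that are also the groups would remove group differences. Clustering used 2000 variable genes chosen without Klrd1, receptor segments, Xist and Y-linked genes, then 30 principal components, 15 neighbours and Leiden resolution 1.0. Clusters of T cells, NK cells and innate lymphoid cells were pooled and clustered again at resolution 1.0. Clusters were named "X-like" from marker lists fixed before the data were examined, but the naming rule was settled after the clusters had been seen and several versions had been tried. A cluster took the name with the most markers among its top 50 genes by fold, with at least 3 such markers. A cluster was left unnamed if its median UMI count was under 0.2 of that of its library, or if another class had more markers among its top 10 genes. CD8 and CD4 T cell markers led the same clusters, so these formed a single conventional T class, and monocyte and macrophage markers did too, so these formed a single monocyte/macrophage class. The rule written for CD8 T cells and for macrophages was applied to these merged classes. A lymphoid cluster with Treg markers in which myeloid genes also led was left unnamed, as was a cluster led by cell-cycle genes. Clusters inside a class were not compared in size, because the genes that lead them differed between the libraries.

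UMIs were summed per library and class and scaled to the UMI total of the class and given as CPM. With 1 library per group there was no test, no p-value and no count of changed genes. Sums were given exact Poisson intervals, shares of cells exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, at 95%. Gene lists were described by the median over members of the difference in log2(CPM + 5), CD94-KO minus WT, among members with at least 20 UMIs over both libraries. Intervals of list medians came from Poisson resampling of the sums. Each median was placed among 10000 random lists of the same size matched on mean expression. A member counted as higher or lower in size at a ratio of at least 1.5-fold. Of the symbols in the lists, 629 were found as written, 9 under an older name, and 24 were not used here. A gene with 0 UMIs in a library was compared with a floor of 3 counts per library.

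Genes were named by a rule fixed before the data were examined. Klrd1, Klrc1, Klrc2, Klrk1, H2-T23, Ifng, Gzmb, Prf1, Pdcd1, Tox, Havcr2, Tigit, Lag3 and Cd274 were always named where they had at least 20 UMIs. By size, the 12 genes with the largest difference in each direction were named in the NK, conventional T and monocyte/macrophage classes, and the 4 largest in each other class of at least 100 cells in both libraries. Ranked genes needed at least 100 UMIs over both libraries, at least 50 CPM in the library where they were higher, and in it at least 0.25 of the CPM of the class where the gene was highest. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Xist, Y-linked and unnamed gene models were left out of the ranking. List examples were the 4 members with the largest difference and the 2 most abundant. Sums over related genes, values of other classes' genes and genomic positions were added after values had been seen. So were the share of a gene's UMIs held by its 10 highest cells, Ccl1 and any other gene outside the rule. Positions are those of GENCODE M21 on GRCm38 (mm10), whose gene identifiers matched the files.

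The interval and list steps were checked on simulated counts drawn from the class means and library sizes, with 100 genes at a true ratio of 2 and 100 at 0.5. These were Poisson counts, the model that the intervals assume, without variation between cells, mice or libraries. They check the calculation only, not whether the model holds for these data. For the NK class, 5973 genes were run, and the median estimates were 1.99 and 0.496, with 96% of each set inside the interval and intervals of 100% and 96% on the correct side of 1. For the conventional T class, 3614 genes were run, with medians of 2.01 and 0.496, 96% and 94% inside, and 100% and 95% on the correct side. For the monocyte/macrophage class, 8978 genes were run, with medians of 2.02 and 0.503, 94% and 91% inside, and 100% and 97% on the correct side. Intervals of unchanged genes excluded 1 in 4.6%, 4.4% and 4.5% of cases in these classes. Of 100 unchanged lists per class, 8%, 6% and 7% fell outside the central 95% of random lists, and a raised list reached percentile 100 in each.

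Alternatives were a mitochondrial limit of 5%, a minimum of 1000 UMIs, doublets kept, Leiden resolution 0.5 or 2.0, each library clustered on its own, classes from a marker score per cell, shares without neutrophils, TMM scaling, a mean over cells that weighs each cell the same, a minimum of 50 UMIs for list members, a pseudocount of 1 CPM and cells thinned to 1000 UMIs. The marker score gives a range, not a type, and 1676 of 8962 cells lay within 0.1 of its threshold of 0.5. Shares of the named immune cells, monocyte/macrophage shares with the largest unnamed cluster counted in, the NK class without its cluster led by heat shock genes and the monocyte/macrophage class without its cluster led by Nos2 were added after the data had been seen. Which results count as main in the closing section was decided after exploratory values had been seen. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only.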

Results

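CD94, encoded by Klrd1, pairs with NKG2 proteins on NK cells and some T cells, and its dimer with NKG2A is an inhibitory receptor for the non-classical MHC class I molecule Qa-1, encoded by H2-T23. The series asks whether loss or blockade of CD94 alters immunity against tumours. The part used here compared live CD45+ cells from subcutaneous tumours of WT mice and of CD94-KO mice, 6 to 8 weeks old, with 1 droplet-based 3′ RNA library per genotype, each derived from 5 tumour-bearing mice. The tumour line was not given in the sources used here. After filtering, 4388 WT cells with 36482364 UMIs and 4574 CD94-KO cells with 42210515 UMIs were compared, at a median of 4768.5 and 7799 UMIs per cell. There were no replicate libraries, so no difference between genotypes could be tested, and each one describes this pair of libraries. Brackets give 95% intervals that cover counting error only, and where an average level of several genes is given it is the median difference in log2(CPM + 5), CD94-KO minus WT.

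Klrd1 was lower in the NK-like cells of the CD94-KO library but was not lost. It stood at 314 CPM [297 to 331] from 1288 UMIs, against 656 CPM [629 to 684] from 2197 UMIs in WT, a ratio of 0.478 [0.446 to 0.513]. Over all kept cells the values were 78.8 CPM [76.1 to 81.5] and 142 CPM [139 to 146], a ratio of 0.553 [0.529 to 0.577]. A Klrd1 UMI was found in 67.7% [63.7 to 71.6] of CD94-KO and 89.1% [85.6 to 92.0] of WT NK-like cells, at median depths of 5775 and 6765.5 UMIs. In the monocyte/macrophage-like cells, which should lack the gene, the shares were 5.96% and 10.6% at median depths of 9980 and 10356 UMIs. With each cell thinned to 1000 UMIs, which left out 11 CD94-KO and 7 WT NK-like cells, the shares were 24.1% [20.6 to 27.9] and 44.2% [39.2 to 49.3] in NK-like cells, and 0.578% and 1.47% in monocyte/macrophage-like cells. Conventional T-like cells had 318 CPM in CD94-KO and 420 CPM in WT (ratio 0.756 [0.668 to 0.855]). Plasmacytoid dendritic (pDC-like) cells had 271 and 435 CPM (ratio 0.623 [0.479 to 0.805]), type 2 conventional dendritic (cDC2-like) cells 230 and 282 CPM (ratio 0.816 [0.739 to 0.902]), and mature regulatory dendritic (mregDC-like) cells 66.3 and 67.9 CPM (ratio 0.977 [0.686 to 1.40]).

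Klrd1 (ENSMUSG00000030165) lies on chromosome 6 at 129591782 to 129598775 on the plus strand of GRCm38 (mm10), with 6 exons in GENCODE M21. Its 3′ untranslated region, 129598467 to 129598775, is part of exon 6. The labels do not say which part of the gene was removed, and 3′ tags of an exon that was kept would still be counted, so the level checks the genotype label only if that end was deleted. The neighbouring genes Klrk1 (129610323 to 129623864), Klrc2 (129647496 to 129660689) and Klrc1 (129666015 to 129678973), which encode NKG2D, NKG2C and NKG2A, lie on the same chromosome.

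**Figure D1:**
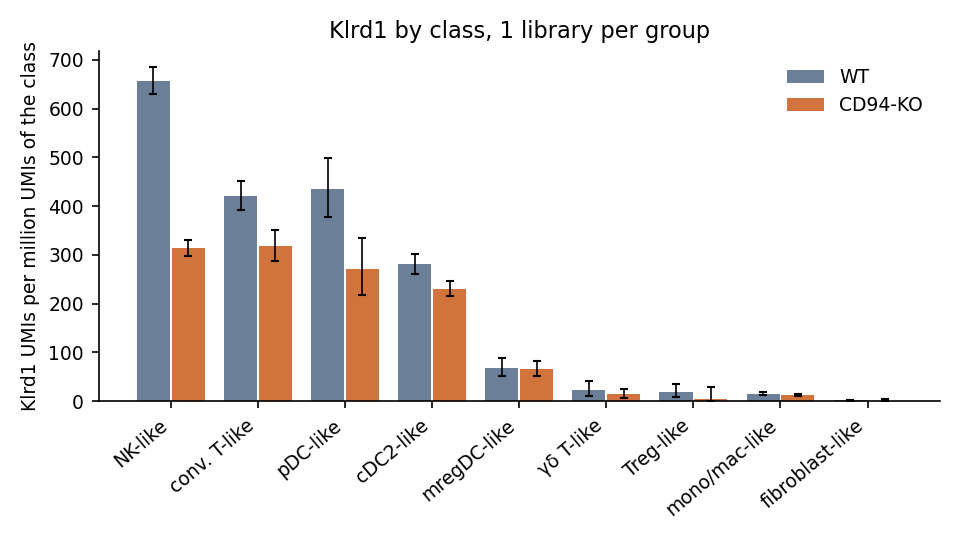
Klrd1 CPM, its UMIs scaled to the UMI total of each class (vertical axis), in the WT and CD94-KO libraries, 1 bar per library and class, with exact 95% Poisson intervals for counting error. The NK-like bars stand at 656 CPM in WT and 314 CPM in CD94-KO, and the monocyte/macrophage-like bars at 15.5 and 12.7 CPM.

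Conventional T-like and regulatory T (Treg-like) cells made up less of the CD94-KO library than of the WT library, under both denominators used. Monocyte/macrophage-like cells made up more of it with the largest unnamed cluster left out of the class, but not with that cluster counted in. Monocyte/macrophage-like cells were 45.5% [44.1 to 47.0] of kept CD94-KO cells and 23.4% [22.2 to 24.7] of kept WT cells, and 56.8% and 45.1% of the named immune cells. That cluster had 2 monocyte/macrophage markers and 2 cell-cycle markers among its top 50 genes, under the minimum of 3 for a name. Counted in, the class was 48.9% [47.5 to 50.4] of kept CD94-KO and 49.5% [48.0 to 51.0] of kept WT cells, with overlapping intervals, and 58.5% and 63.5% of named immune cells with the cluster. Conventional T-like cells were 3.56% [3.05 to 4.14] and 5.63% [4.97 to 6.35] of kept cells, and 4.44% and 10.8% of named immune cells. Treg-like cells were 0.940% [0.681 to 1.26] and 2.03% [1.63 to 2.49] of kept cells, 43 and 89 cells. NK-like cells were 12.4% [11.5 to 13.4] in CD94-KO and 8.98% [8.15 to 9.86] in WT of kept cells but 15.5% and 17.3% of named immune cells, so their direction depended on the denominator.

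Relative to each other, there were 3.48 [2.92 to 4.17] NK-like cells per conventional T-like cell in CD94-KO and 1.60 [1.36 to 1.88] in WT, and 13.2 [9.66 to 18.4] and 4.43 [3.51 to 5.64] per Treg-like cell. The number of conventional T-like cells per Treg-like cell was 3.79 [2.69 to 5.44] and 2.78 [2.17 to 3.58], and intervals overlapped. Neutrophil-like cells were 2.08% [1.68 to 2.53] of kept CD94-KO cells and 0.729% [0.499 to 1.03] of kept WT cells. Gamma-delta T-like cells, marked by Il17a and Cd163l1, were 3.41% [2.90 to 3.98] and 2.12% [1.71 to 2.59], but 4.25% and 4.08% of named immune cells. Dendritic classes followed the denominator too, with cDC2-like cells at 6.71% and 4.81% of kept cells but 8.37% and 9.26% of named immune cells, and mregDC-like cells at 3.39% and 2.55% but 4.23% and 4.91%. The pDC-like cells were lower in CD94-KO under both, at 0.634% [0.425 to 0.909] and 1.0% [0.73 to 1.34] of kept cells, with overlapping intervals. Of named immune cells they were 0.790% and 1.93%. Mast or basophil-like cells were 30 in CD94-KO and 4 in WT, but 0.984% and 1.0% of cells with classes from a marker score. There were 32 and 22 B-like cells, and 10 and 3 type 2 innate lymphoid (ILC2-like) cells. Fibroblast-like cells, led by Sparc, Col3a1 and Col1a2, were 2.03% in CD94-KO and 4.19% in WT despite the CD45 sort.

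Unnamed clusters, kept out partly by a naming threshold set after the clusters had been seen, held 17.8% of CD94-KO and 43.9% of WT cells. The largest, led by AY036118 and Gm42418 at median depths of 698 and 646 UMIs, held 3.39% of CD94-KO and 26.1% of WT cells. A cluster led by Trps1 and Neat1 held 8.20% and 7.89%, and a lymphoid cluster led by Txk and Bcl2 held 2.47% and 4.40%. The cluster that carried Treg and myeloid genes together held 2.49% and 3.87%, at 16166.5 and 21709.5 UMIs per cell, and the cell-cycle cluster 1.20% and 1.62%. All shares were taken after a CD45 sort and across a gap in median depth. Among cells with at least 1000 UMIs, NK-like cells were 14.6% in CD94-KO and 15% in WT, and with each library clustered on its own conventional T-like cells were 3.63% and 2.44%, the opposite order.

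**Figure D2:**
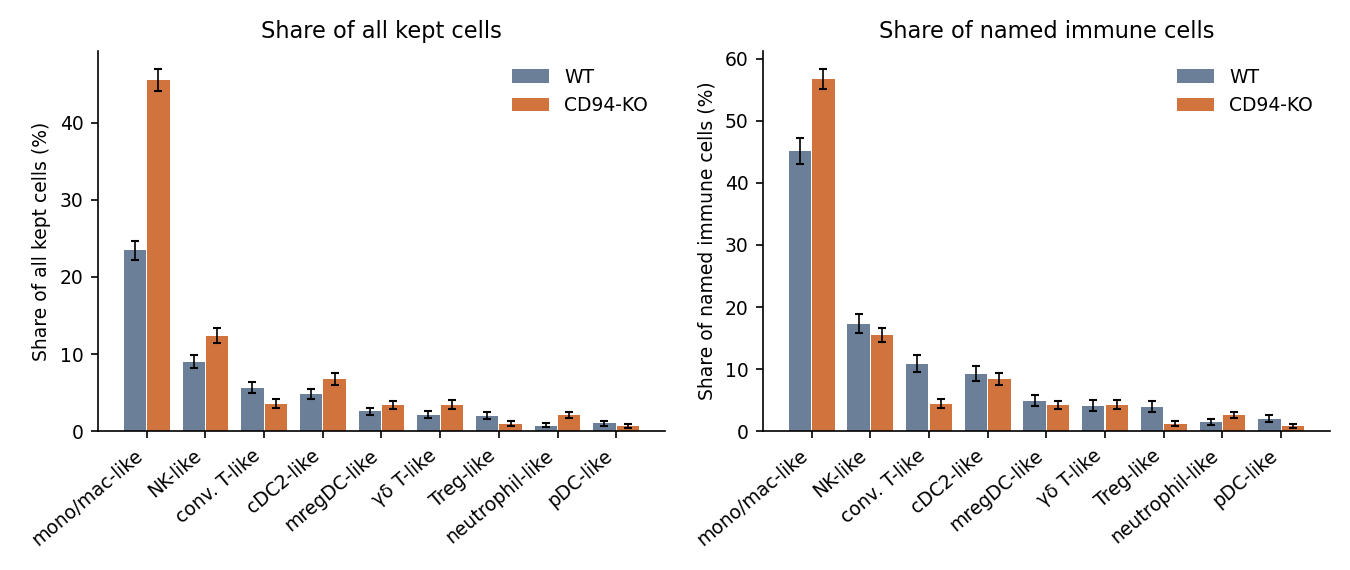
Share of all kept cells (left, percent) and of the named immune cells (right, percent) in each class, 1 bar per library, with exact 95% Clopper-Pearson intervals for counting error. Monocyte/macrophage-like cells stand higher in CD94-KO on both sides, 45.5% against 23.4% on the left and 56.8% against 45.1% on the right, but not (48.9% against 49.5%, and 58.5% against 63.5%) with the largest unnamed cluster counted among them, and the NK-like bars change order between the sides.

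In the NK-like cells, 394 in WT and 567 in CD94-KO, Ifng and Fasl were higher in the CD94-KO library, while the lists of cytotoxic effectors and of effector cytokines lay within the central 95% of random lists. Ifng, which encodes interferon gamma, was at 328 CPM against 188 CPM in WT (ratio 1.74 [1.59 to 1.92]). Fasl, the ligand of the death receptor Fas, was at 105 against 55.6 CPM (ratio 1.89 [1.59 to 2.26]), and Prf1, the pore-forming protein perforin, at 367 against 280 CPM (ratio 1.31 [1.21 to 1.42]). Granzyme B (Gzmb) was slightly lower, 1384 against 1493 CPM (ratio 0.927 [0.893 to 0.964]). The chemokine receptor gene Cxcr4 was at 146 against 78.9 CPM (ratio 1.85 [1.60 to 2.15]), and the chromatin regulator Kmt2a at 176 against 99.2 CPM (ratio 1.77 [1.56 to 2.03]).

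Beyond these, Mapk6, Cnot6, Zfr, Arid4a, Kmt2c, Pcm1 and Kdm7a were higher by size, with ratios of 1.75 to 1.91. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892, plus strand) leads a cluster inside the class together with heat shock genes, so it is given for the whole class. By cluster it was higher in CD94-KO in that cluster (903 against 560 CPM) and in the one led by Gzma (353 against 178 CPM), but lower in the one led by Gzmc (57.3 against 159 CPM), and over the class 10 cells held 39.9% of its UMIs in CD94-KO and 39.0% in WT. The CD94 partners Klrc1 and Klrc2, the ligand gene H2-T23 and Klrk1, whose product does not pair with CD94, had ratio intervals that included 1. Ratios of single genes were not TMM scaled, which would shift values of this class by -0.12, so inclusion of 1 depends on the scaling. Klrc1 was at 176 against 163 CPM (ratio 1.08 [0.963 to 1.21]), Klrc2 at 91.1 against 89.0 CPM (ratio 1.02 [0.877 to 1.20]), Klrk1 at 371 against 377 CPM (ratio 0.983 [0.912 to 1.06]), and H2-T23 at 222 against 227 CPM (ratio 0.978 [0.887 to 1.08]). Klrc1 and Klrc2 are near-identical in parts, so their split is uncertain. Cd274, which encodes PD-L1, was at 85.8 against 60.0 CPM (ratio 1.43 [1.20 to 1.71]). Its level was far higher in neutrophil-like and mregDC-like cells, and whether free RNA added to the NK-like counts was not tested. Pdcd1, which encodes PD-1, was at 14.9 against 43.0 CPM (ratio 0.346 [0.252 to 0.469]), with 95.1% and 92.4% of its UMIs in 10 cells, and its log2 difference of -1.27 became -0.20 with classes from a marker score. Tox (15.8 against 14.3 CPM), Havcr2 (10.2 against 7.77 CPM), Tigit (9.75 against 7.17 CPM) and Lag3 (13.6 against 18.8 CPM) had ratio intervals that included 1.

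Granzymes of the Gzmc to Gzmg group, serine proteases of activated NK and T cells, went in different directions. Gzmf was at 429 against 133 CPM (ratio 3.23 [2.91 to 3.59]), but 10 cells held 99.7% and 98.2% of its UMIs, and its log2 difference of 1.66 became -0.21 with each cell weighed the same and 0.15 with classes from a marker score. Gzmc was at 3181 against 4352 CPM (ratio 0.731 [0.714 to 0.749]) and Gzmg at 78.7 against 142 CPM (ratio 0.556 [0.481 to 0.642]). The Gzmg UMIs lay in 13 CD94-KO and 9 WT cells, 2.29% and 2.28% of the class. The log2 difference of Gzmg went from -0.81 to -2.02 with the marker score. These genes are close copies on chromosome 14, with Gzmg at 56156582 to 56159579, Gzmf (ENSMUSG00000015441) at 56205263 to 56211417 and Gzmc at 56231441 to 56234656, all on the minus strand. They lead a cluster inside the class and their single values are uncertain. Summed over Gzmc, Gzmd, Gzme, Gzmf and Gzmg, the class had 4174 CPM in CD94-KO and 5169 CPM in WT (ratio 0.808 [0.791 to 0.825]). Because these genes lead a cluster inside the class, their sum depends on the make-up of the class. Other genes lower in CD94-KO by size were Klrd1, Polr2l (54.8 against 98.3 CPM), Erdr1 (44.3 against 78.9 CPM), AY036118 (688 against 962 CPM), Lamtor1, Dctpp1, Dynlrb1, Hat1, Fkbp4 and Snhg12. AY036118 was also lower by size in conventional T-like, cDC2-like and monocyte/macrophage-like cells. So were Polr2l in conventional T-like and monocyte/macrophage-like cells and Erdr1 in cDC2-like and monocyte/macrophage-like cells. These genes are thus not particular to NK-like cells, and a difference between the libraries cannot be told apart.

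Among 9405 genes of the NK-like class the median difference was 0.10, and 0.01 after TMM scaling, which shifted values by -0.12. List medians and ratios of single genes are to be read against that shift. Interferon gamma response genes had a median of 0.29 [0.20 to 0.40], at percentile 99.8 of the random lists, a rank that describes these libraries, with 5 of 27 measured members at least 1.5-fold higher and 0 lower. Gbp5 (31.4 against 14.9 CPM), Gbp3 (55.8 against 34.7 CPM) and Socs1 (41.7 against 26.0 CPM) were among them. Chemokine receptor and trafficking genes had a median of 0.28 [0.21 to 0.39] at percentile 99.6, with Cxcr4, S1pr1 (45.1 against 25.7 CPM) and S1pr5 (7.31 against 1.79 CPM) among the members higher by size. NK maturation genes had a median of 0.21 [0.17 to 0.41] at percentile 94.8, with S1pr5, the mast cell protease homologue Cma1 (40.2 against 19.4 CPM) and Rap1gap2 higher by size of 14 members. TMM scaling gave 0.18, 0.16 and 0.11 for these lists, and the interferon gamma response median was 0.12 with classes from a marker score. Cytotoxic effectors stood at 0.12 [-0.08 to 0.19], percentile 87.8, with Gzmf and Fasl higher by size of 17 members, and the sign was lost under TMM (0.00) and turned with each cell weighed the same (-0.06).

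The CD94/NKG2 family had a median of 0.04 [-0.04 to 0.12], percentile 37.8, which turned to -0.07 under TMM, and 0 of its 8 members passed 1.5-fold. Ly49 receptors had 0.17 [-0.04 to 0.22], percentile 83.9, with 0 of 8 members past 1.5-fold. UMIs summed over 11 numbered Klra genes gave 1382 and 1369 CPM (ratio 1.01 [0.971 to 1.05]). Inhibitory receptor and exhaustion genes had 0.20 [-0.02 to 0.37], percentile 89.8, with the T-box factor Eomes (326 against 205 CPM) and Entpd1 higher and Pdcd1 lower of 15. Effector cytokines and chemokines had -0.07 [-0.16 to 0.08], percentile 8.9, and 0.03 with each cell weighed the same. Ifng was higher and the chemokine gene Ccl1 lower, with 0 UMIs in CD94-KO against 87 UMIs in 11 WT cells. The floor of 3 counts per library gives 35.5-fold, but 10 WT cells held 98.85% of these UMIs. That fold treats UMIs as independent and is therefore no lower bound. By cells, 0% in CD94-KO and 2.79% in WT held a Ccl1 UMI. Activation and costimulation genes stood at 0.22, percentile 96.5, with Cd38 higher of 17, and 0.07 with the marker score. Naive and memory genes stood at 0.11, percentile 58.8, with S1pr1 among the members higher by size, and immature NK and ILC1 genes at 0.01, percentile 13.6, which became -0.09 under TMM. Tissue residency genes stood at 0.18, percentile 92.8, with Rgs10 lower of 12, and CD4 T helper genes at 0.35, percentile 99.2, with Ifng higher of 10.

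Type I interferon response genes stood at 0.20, percentile 95.5, with 4 of 28 members higher by size in NK-like cells, but 22 of the 28, and 3 of those 4, were below 0.25 of the level of the class where they were highest. TGF-beta response genes stood at 0.26, percentile 96.1, with Smurf2 higher of 13. Proliferation genes were on balance lower, at -0.13, percentile 0.1, with Mcm5 (22.9 against 40 CPM), Tyms (12.2 against 22.1 CPM) and Tk1 among 4 lower of 21, though the median was 0.01 with each cell weighed the same. Glycolysis and hypoxia genes stood at -0.08, percentile 0.5, with Eno1 at 334 against 450 CPM, and oxidative phosphorylation genes at -0.03, percentile 10.7. MHC class I genes stood at -0.05, percentile 4.5, and MHC class II genes at 0.04, percentile 24, which became -0.08 under TMM. Heat shock and dissociation genes stood at 0.17, percentile 97.4, with Hspa1a, Hspa1b and Hsph1 higher of 24. Hspa1a was lower in CD94-KO inside the cluster that it helps to lead (1761 against 2399 CPM) and close to level in the one led by Gzma (25.3 against 26.9 CPM), but higher in the one led by Gzmc (81.2 against 12.5 CPM), so its class value depends on the make-up of the class. Apoptosis and cell stress genes stood at 0.17, percentile 77.5. Myeloid and Treg lists lay within the central 95% of random lists in NK-like cells, with inflammatory macrophage genes at 0.18 (percentile 89.3), alternatively activated macrophage genes at 0.13 (percentile 73.6), suppressive neutrophil genes at 0.20 (percentile 95.1), mature neutrophil genes at 0.24 (percentile 92.9) and Treg effector genes at -0.02 (percentile 6.6). With the marker score the first 3 turned to -0.41, -0.31 and -0.22, and without the heat shock cluster the inflammatory macrophage and suppressive neutrophil medians were -0.08 and -0.02. Of the myeloid genes themselves, Ccl24 was at 27.8 against 5.97 CPM, Arg1 at 78.0 against 35.5 CPM and Nos2 at 8.53 against 2.09 CPM, while Lyz2 was at 229 against 296 CPM. Of the 27 interferon gamma response genes, 16 were below 0.25 of the level of the class where they were highest, among them 2 of the 5 higher ones. Ribosomal protein transcripts took 28.2% of NK-like UMIs in CD94-KO and 31.9% in WT, and Malat1 was at 21300 and 16020 CPM.

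**Figure D3:**
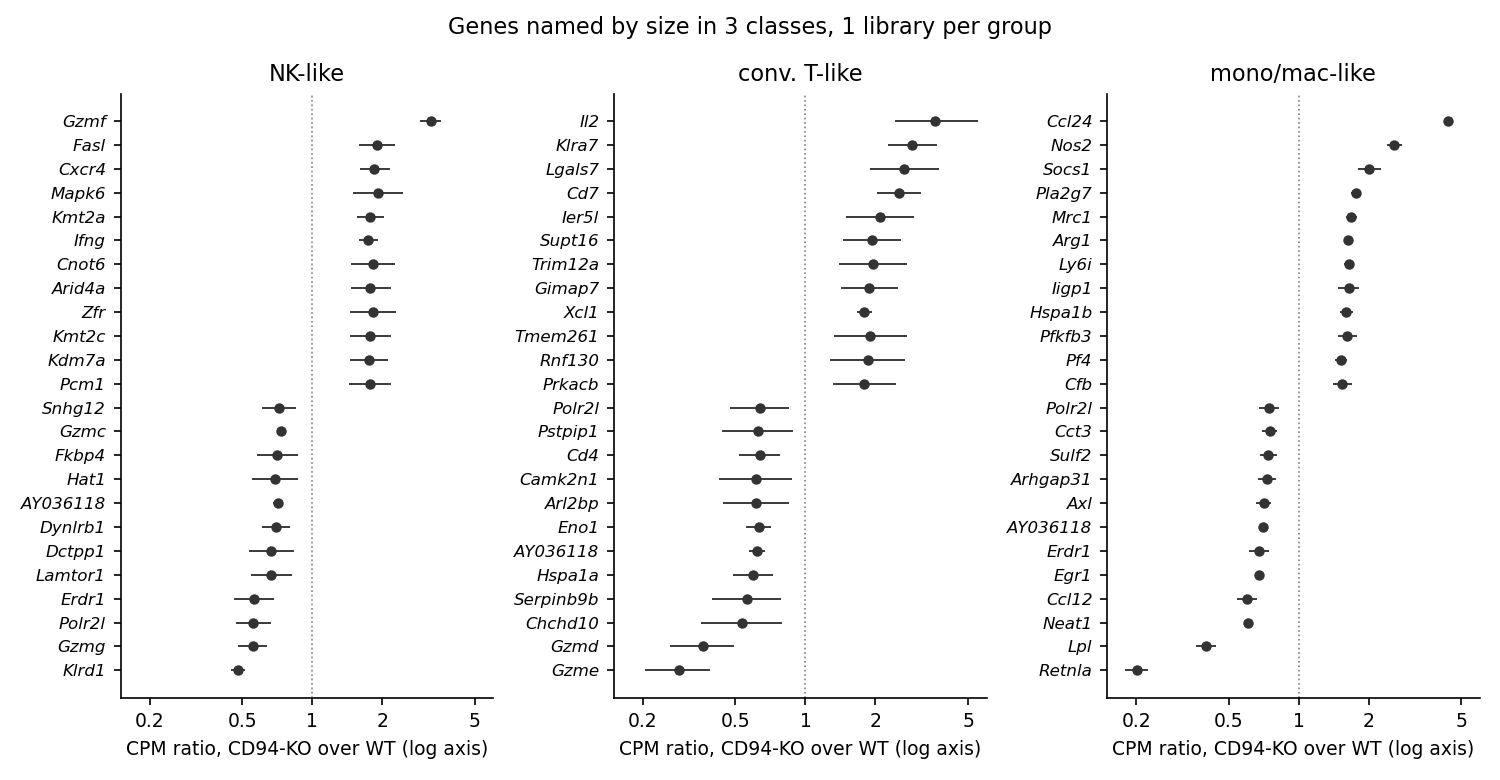
Ratio of CPM, CD94-KO over WT (horizontal log axis), of the genes named by size in the NK-like, conventional T-like and monocyte/macrophage-like classes, with exact 95% intervals for counting error and a dotted line at 1. Gzmf (3.23), Il2 (3.62) and Ccl24 (4.38) stand farthest to the right in their panels and Klrd1 (0.478), Gzme (0.285) and Retnla (0.201) farthest to the left, and Gzmf falls below 1 when each cell weighs the same.

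In the conventional T-like cells, 247 in WT and 163 in CD94-KO, Ly49 receptor genes, which encode MHC class I receptors of NK cells and some T cells, were higher in the CD94-KO library. Of 6 measured members 5 were at least 1.5-fold higher, with a median of 0.79 [0.60 to 1.14] at percentile 100. That median was 0.26 with the marker score, 0.40 with at least 1000 UMIs and 2.55 with each library clustered on its own. The sum over Klra genes was 433 against 215 CPM (ratio 2.02 [1.77 to 2.30]). Of other genes typical of NK cells, Klre1 (178 against 117 CPM) and Eomes (41.0 against 24.3 CPM) were higher by size too, while Gzma was lower (374 against 548 CPM). The chemokine gene Xcl1 was at 1085 against 605 CPM (ratio 1.79 [1.66 to 1.94]), and the lectin gene Lgals7, the surface receptor gene Cd7 and the immune GTPase gene Gimap7 were at 80.3, 188 and 93.4 CPM against 30.1, 74.5 and 49.7 CPM. Il2 was at 68.8 against 19.0 CPM (ratio 3.62 [2.42 to 5.50]), from 84 UMIs in 5 CD94-KO cells and 36 UMIs in 7 WT cells. Lower in CD94-KO were Gzme (39.3 against 138 CPM, ratio 0.285 [0.205 to 0.389]), Gzmd (41.8 against 116 CPM, ratio 0.361 [0.261 to 0.491]), the serpin gene Serpinb9b (40.1 against 71.4 CPM) and Cd4 (113 against 178 CPM). For Cd4, 10 cells held 51.5% of the UMIs in CD94-KO and 44.2% in WT. Cells with UMIs of Cd4 but not of Cd8 were close in share, 25.15% in CD94-KO and 26.72% in WT. Cells with UMIs of neither were 42.94% in CD94-KO and 40.08% in WT. Which cells of the class carried the Ly49, Klre1 and Eomes UMIs was not tested.

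Among the checkpoint genes of the conventional T-like cells, Pdcd1 was at 235 against 321 CPM (ratio 0.733 [0.635 to 0.845]), Lag3 at 78.6 against 90.4 CPM, Havcr2 at 36.9 against 46.0 CPM, Tigit at 4.10 against 8.99 CPM and Tox at 28.7 against 29.1 CPM, and the intervals of the last 4 ratios included 1. Gzmb was at 754 against 768 CPM, Prf1 at 78.6 against 66.6 CPM and Ifng at 315 against 272 CPM (ratio 1.16 [1.01 to 1.32]). Ratios in this class were not TMM scaled, which would shift values by -0.09. By cluster Ifng was lower in CD94-KO in the one led by Cd3d (109 against 193 CPM). It was higher in the one led by Ccl1 (641 against 354 CPM), so its class value depends on the make-up of the class. Klrc1 was at 269 against 272 CPM, Klrc2 at 73.7 against 70.3 CPM, Klrk1 at 240 against 216 CPM, H2-T23 at 274 against 314 CPM and Cd274 at 83.6 against 53.9 CPM (ratio 1.55 [1.17 to 2.06]). Cytotoxic effectors had a median of -0.03 [-0.22 to 0.03], percentile 16.2, with Gzmd, Gzme and Serpinb9b lower by size and 0 higher of 17, and -0.47 with each library clustered on its own, and the Gzmc to Gzmg sum was 676 against 1094 CPM (ratio 0.618 [0.569 to 0.670]). Of these granzymes only Gzmf was measured by cluster. It was at 573 against 600 CPM in the cluster led by Ccl1 and 0 against 6.26 CPM in the one led by Cd3d. The class value of Gzmf thus depends on the make-up of the class. Inhibitory receptor and exhaustion genes had -0.04 [-0.21 to 0.12], percentile 12.1, 0.05 with each cell weighed the same and -0.51 with each library clustered on its own. Effector cytokines and chemokines had -0.18 [-0.43 to 0.01], percentile 0.4, with Xcl1 and Il2 higher and Ccl4 (296 against 748 CPM), Ccl1 and Il10 lower of 13. The median turned to 0.10 with a mitochondrial limit of 5% and 0.14 with at least 1000 UMIs. Naive and memory genes had 0.28 [0.08 to 0.39], percentile 99.6, with Slamf6 (28.7 against 15.9 CPM) higher by size and the memory factor Tcf7 at 117 against 87.8 CPM. Glycolysis and hypoxia genes had -0.28 [-0.36 to -0.20], percentile 0.0, with Eno1 (285 against 453 CPM, ratio 0.629 [0.554 to 0.714]), Pgk1, Pfkl and Bnip3 lower and Vegfa (114 against 61.3 CPM) higher of 23. Their median was -0.06 with the marker score and -0.82 with each library clustered on its own. Chemokine receptor and trafficking genes had 0.31 [0.11 to 0.42], percentile 100, and 0.54 with each library clustered on its own. Of 15 members, Cxcr4 (91.8 against 46.5 CPM) and the integrin gene Itga4 (157 against 93.6 CPM) were higher by size. Both Cxcr4 and Itga4 were below 0.25 of the level of the class where they were highest. Interferon gamma response genes had 0.08, which became 0.00 under TMM.

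The remaining genes named by size were Klra7, Ier5l, Supt16, Trim12a, Tmem261, Rnf130 and Prkacb, higher in CD94-KO, and Chchd10, Hspa1a, AY036118, Arl2bp, Camk2n1, Pstpip1 and Polr2l, lower. Several macrophage transcripts in the conventional T-like cells were lower in CD94-KO, with Spp1 at 44.2 against 106 CPM, C1qa at 25.4 against 56.6 CPM and Apoe at 60.6 against 125 CPM, while Ccl24 (32.8 against 12.7 CPM) and Vegfa were higher. Alternatively activated macrophage genes had a median of -0.25 there, which turned to 0.72 with the marker score. Many values rested on few cells, since 10 cells held 74.4% and 61.0% of the Klra7 UMIs, 69.0% and 41.9% of the Xcl1 UMIs and all or nearly all of the Gzmd and Gzme UMIs. With each library clustered on its own, the log2 difference of Klra7 moved from 1.45 to 3.74, of Pdcd1 from -0.44 to -1.40 and of Ifng from 0.21 to -0.20. In the same setting the naive and memory median became 1.25, and Hspa1a turned from -0.72 to 0.07. With the marker score Klra7 went to 0.26 and Il2 from 1.62 to 0.19.

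In the monocyte/macrophage-like cells, 1028 in WT and 2082 in CD94-KO, interferon response genes had positive medians over the class, which were smaller without its cluster led by Nos2, and single genes of alternative activation went in both directions. Ccl24, an eotaxin-family chemokine gene, was at 960 against 219 CPM (ratio 4.38 [4.21 to 4.56]), and Nos2, the inducible nitric oxide synthase, at 191 against 73.8 CPM (ratio 2.58 [2.40 to 2.78]). Arg1, arginase 1, was at 2853 against 1745 CPM (ratio 1.63 [1.61 to 1.66]), Mrc1, the mannose receptor, at 225 against 134 CPM (ratio 1.68 [1.59 to 1.78]), and the cytokine signalling inhibitor Socs1 at 64.1 against 31.9 CPM (ratio 2.01 [1.79 to 2.25]). Retnla, a marker of alternative activation, was at 18.1 against 89.8 CPM (ratio 0.201 [0.180 to 0.226]), and the lipoprotein lipase gene Lpl at 30.9 against 77.5 CPM (ratio 0.398 [0.361 to 0.440]).

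Also higher by size were Pla2g7, Ly6i, Hspa1b, Pf4, the complement gene Cfb, the interferon-inducible GTPase gene Iigp1 and the glycolytic regulator Pfkfb3, with ratios of 1.52 to 1.76. Also lower were Neat1 (273 against 451 CPM), the chemokine gene Ccl12 (38.3 against 63.7 CPM), the immediate early gene Egr1 (385 against 571 CPM), Axl (67.5 against 95.6 CPM), Erdr1, AY036118 (642 against 917 CPM), Arhgap31, Sulf2, Cct3 and Polr2l. Cd274 was at 311 against 242 CPM (ratio 1.28 [1.23 to 1.34]), H2-T23 at 427 against 357 CPM (ratio 1.20 [1.15 to 1.24]) and Havcr2 at 127 against 109 CPM (ratio 1.16 [1.09 to 1.24]). Ccl24 (ENSMUSG00000004814) lies on chromosome 5 at 135569937 to 135573049, minus strand, and Nos2 (ENSMUSG00000020826) on chromosome 11 at 78920787 to 78960254, plus strand. Arg1 (ENSMUSG00000019987) lies on chromosome 10 at 24915221 to 24927484, minus strand, and Retnla (ENSMUSG00000061100) on chromosome 16 at 48842551 to 48844461, plus strand. Each of these 4 genes leads a cluster inside the class, so they are given for the class as a whole. Ccl24 was higher in CD94-KO in the cluster that it leads (2111 against 292 CPM) and in the one led by Hp (63.8 against 22.4 CPM), but lower in those led by Nos2 (90.0 against 108 CPM) and Retnla (211 against 377 CPM). Arg1, Mrc1, Pf4, Lpl, Ccl12 and Ly6i are among the markers that named it.

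Interferon gamma response genes had a median of 0.30 [0.22 to 0.33] in monocyte/macrophage-like cells, percentile 100, with Iigp1, Socs1 and Nos2 higher by size and 0 lower of 31. Irgm1 was at 145 against 96.9 CPM and Cxcl9 at 1118 against 1067 CPM, although Cxcl9 was lower in CD94-KO inside each of the 4 clusters of the class (2578 against 2829 CPM in the one led by Nos2), so its class value depends on the make-up of the class. Type I interferon response genes had 0.17 [0.13 to 0.21], percentile 100, with 0 of 34 past 1.5-fold. MHC class I genes had 0.10 [0.07 to 0.13], percentile 99, with B2m at 4095 against 3465 CPM, and MHC class II genes 0.12 [0.07 to 0.14], percentile 99.3, with Ctss at 2899 against 2295 CPM and H2-Ab1 at 4140 against 3581 CPM. With a mitochondrial limit of 5% the interferon gamma response, MHC class I and MHC class II medians were 0.15, 0.02 and 0.06, and with doublets kept 0.20, 0.03 and 0.05. Without the cluster led by Nos2 they were 0.12, 0.02 and -0.00 and the type I interferon response median was 0.09, so these medians depend on the make-up of the class. Alternatively activated and tissue macrophage genes had 0.07 [0.02 to 0.12], percentile 98.5, with Arg1, Mrc1, Cd163, Ccl24 and Maf higher and Retnla lower of 32, and the median turned to -0.02 with classes from a marker score and was 0.13 without the cluster led by Nos2. Inflammatory macrophage genes had -0.01 [-0.05 to 0.04], percentile 20.4, with Nos2 and Ccl5 (467 against 309 CPM) higher of 24, while Il1b was at 5156 against 6278 CPM and Il6 at 16.7 against 27.0 CPM, and the median was 0.04 with each cell weighed the same. Glycolysis and hypoxia genes had 0.12 [0.10 to 0.14], percentile 99.9, with Hilpda at 358 against 232 CPM, and 0.01 with a mitochondrial limit of 5% or without the cluster led by Nos2. Activation and costimulation genes had -0.20 [-0.26 to -0.09], percentile 0.0, with Tnfrsf4 lower by size of 18. Effector cytokines and chemokines had -0.18 [-0.25 to -0.12], percentile 0.0, with Ccl5 higher and Xcl1 lower of 11, and -0.02 at Leiden resolution 2.0. Of these members, 14 of 18 and 9 of 11 were below 0.25 of the level of the class where they were highest. Both medians thus rest mostly on genes that are higher in other classes, and free RNA was not tested as a source. Several transcripts of lymphoid cells were also lower in this class in CD94-KO. Gzmc was at 10.6 against 25.1 CPM, Nkg7 at 10.8 against 19.3 CPM and Xcl1 at 6.32 against 14.9 CPM. Gzma was level (26.4 against 26.8 CPM). Ly49 receptor genes had a median of -0.11 [-0.28 to 0.02], percentile 1.4, with 0 of 7 measured members past 1.5-fold. The sum over 11 numbered Klra genes, against 10 genes in the Ly49 list, was 157 against 149 CPM.

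The value of Retnla rested on few cells, since 10 cells held 90.1% of its UMIs in CD94-KO and 98.0% in WT, and its log2 difference of -2.04 was -1.05 with each cell weighed the same. For Ccl24 the share in 10 cells was 20.7% and 41.3%, for Nos2 13.2% and 30.8%, and for Ccl12, lower in CD94-KO, 33.11% and 66.15%. The log2 difference of Nos2 was 1.31, 0.30 with a mitochondrial limit of 5% and 0.49 with doublets kept, that of Ccl24 was 2.11 and 2.92 with the marker score, and that of Pf4 turned from 0.58 to -0.08 with the marker score.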

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

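The shares of named immune cells, the monocyte/macrophage-like share with the largest unnamed cluster counted in, the NK-like class without its cluster led by heat shock genes and the monocyte/macrophage-like class without its cluster led by Nos2 were chosen after the data had been seen. The other alternatives were set before. No paired analysis was possible because there was 1 library per group, and for the same reason no library could be left out in turn. For the 6 main class shares, 40 alternative values stayed within the counting interval of the main value, 10 moved outside it and 5 changed sign although the main interval excluded 0. Changes of sign where the main interval included 0 are counted among the values inside or outside that interval. For the 13 main list medians these 3 numbers were 127, 23 and 2, for the 119 other list medians 1163, 152 and 37, and for 143 gene values 1212, 205 and 13. The log2 ratio of the share of NK-like cells with a Klrd1 UMI went from -0.40 to -0.87 with cells thinned to 1000 UMIs. The 13 class shares stayed within their intervals at both other Leiden resolutions. Depth limits the comparison of shares, since 29.9% of kept WT and 7.08% of kept CD94-KO cells had under 1000 UMIs. For the values that follow, each a log2 ratio or a median log2 difference, the cause was not tested, except that the share of named immune cells differs by its denominator alone and the share with the unnamed cluster by those cells alone.

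As shares of the named immune cells, NK-like went from 0.47 to -0.16, conventional T-like from -0.66 to -1.29, Treg-like from -1.11 to -1.74, monocyte/macrophage-like from 0.96 to 0.33, gamma-delta T-like from 0.69 to 0.06, cDC2-like from 0.48 to -0.15, mregDC-like from 0.41 to -0.22 and neutrophil-like from 1.51 to 0.88. With the largest unnamed cluster counted in, the monocyte/macrophage-like share was -0.02 of kept cells and -0.12 of named immune cells with the cluster. With at least 1000 UMIs the NK-like share was -0.03, the conventional T-like share -1.14 and the monocyte/macrophage-like share 0.56, NK maturation in NK-like cells went from 0.21 to 0.16, effector cytokines in conventional T-like cells from -0.18 to 0.14, Gzmb in cDC2-like cells from -0.51 to 0.04 and Ifng in monocyte/macrophage-like cells from -0.30 to 0.42. The monocyte/macrophage-like share was 0.78 with a mitochondrial limit of 5% and 0.82 with doublets kept.

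With each library clustered on its own, the conventional T-like share was 0.57. Effector cytokines went from -0.07 to -0.16 in NK-like and from -0.27 to 0.06 in cDC2-like cells, and suppressive neutrophil genes in cDC2-like cells from -0.13 to 0.10. In conventional T-like cells cytotoxic effectors went from -0.03 to -0.47, inhibitory receptors from -0.04 to -0.51, naive and memory genes from 0.28 to 1.25, proliferation from 0.17 to -0.20, Hspa1a from -0.72 to 0.07 and Ifng from 0.21 to -0.20. In mregDC-like cells cytotoxic effectors went from -0.56 to 0.23 and Gzmb from -1.21 to 0.35.

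With classes from a marker score, the mast or basophil-like share went from 2.85 to -0.03 and the neutrophil-like share to 0.81. In NK-like cells NK maturation was 0.14, inflammatory macrophage genes went from 0.18 to -0.41 and suppressive neutrophil genes from 0.20 to -0.22. In cDC2-like cells cytotoxic effectors went from 0.29 to -0.03, type I interferon response from -0.13 to 0.07, glycolysis from 0.20 to -0.09, oxidative phosphorylation from -0.04 to 0.01 and heat shock from -0.04 to 0.04. In conventional T-like cells the CD94/NKG2 family went from 0.23 to -0.11, inflammatory macrophage genes from -0.14 to 0.23, alternatively activated macrophage genes from -0.25 to 0.72, suppressive neutrophil genes from -0.23 to 0.34, Treg effector genes from -0.17 to 0.03, H2-T23 from -0.20 to 0.07 and Ifng to -0.74. In monocyte/macrophage-like cells NK maturation went from 0.04 to -0.00, MHC class II from 0.12 to 0.18, alternatively activated macrophage genes from 0.07 to -0.02, mature neutrophil genes from -0.06 to 0.41, TGF-beta response from 0.05 to -0.04 and Pf4 from 0.58 to -0.08. In mregDC-like cells MHC class II went from -0.18 to 0.06 and chemokine receptors from 0.17 to -0.20.

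With a mitochondrial limit of 5%, effector cytokines in conventional T-like cells were 0.10, and in monocyte/macrophage-like cells interferon gamma response went from 0.30 to 0.15, MHC class II to 0.06, inflammatory genes from -0.01 to -0.07 and mature neutrophil genes to 0.03. In mregDC-like cells cytotoxic effectors went to 0.16, alternatively activated macrophage genes from -0.23 to 0.17 and Gzmb to 0.18, and Ly6i in cDC2-like cells went from 0.85 to -0.13. With doublets kept, interferon gamma response was 0.20, MHC class II 0.05 and mature neutrophil genes 0.01 in monocyte/macrophage-like cells, and in mregDC-like cells alternatively activated macrophage genes were 0.83, mature neutrophil genes went from -0.56 to 0.71 and Gzmb to 1.25.

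Under TMM scaling the CD94/NKG2 family in NK-like cells went from 0.04 to -0.07, effector cytokines to -0.19 and NK maturation to 0.11, and interferon gamma response in conventional T-like cells from 0.08 to -0.00. With each cell weighed the same, conventional T-like values became -0.04 for the CD94/NKG2 family, -0.00 for CD4 T helper genes and -0.10 for proliferation. Monocyte/macrophage-like values became 0.17 for MHC class II and 0.04 for inflammatory genes, mregDC-like values 0.02 for alternatively activated macrophage genes and 0.08 for oxidative phosphorylation, and Gzmf in NK-like cells went from 1.66 to -0.21. Without the heat shock cluster, NK-like values were -0.19 for effector cytokines, -0.08 for inflammatory macrophage genes and -0.02 for suppressive neutrophil genes. Without the cluster led by Nos2, monocyte/macrophage-like values were 0.12 for interferon gamma response, -0.00 for MHC class II and 0.13 for alternatively activated macrophage genes. With members of at least 50 UMIs, mature neutrophil genes in NK-like cells went from 0.24 to -0.12. Leiden resolution 0.5 gave 0.14 for type I interferon response in cDC2-like cells, and resolution 2.0 gave 0.06 for inflammatory genes and 0.03 for Ifng in monocyte/macrophage-like cells.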

Other observations

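The tests of mitochondrial share, of Klrd1 across classes, of Ptprc and of Y-linked genes were chosen after their results had been seen, and the remaining tests were written down before. In the mregDC-like cells, 112 in WT and 155 in CD94-KO, inducible heat shock genes were far higher in the CD94-KO library. Hspa1a was at 603 against 81.2 CPM and its near-copy Hspa1b at 680 against 112 CPM, and their sum was 1283 against 193 CPM (ratio 6.66 [5.65 to 7.89]). Heat shock and dissociation genes had a median of 0.52 [0.36 to 0.59] at percentile 100, with 8 of 24 at least 1.5-fold higher and 0 lower, among them the co-chaperone gene Dnajb1 at 104 against 42.4 CPM. The same pair of Hspa1 genes summed to 513 against 312 CPM in NK-like cells and 362 against 238 CPM in monocyte/macrophage-like cells, but to 361 against 447 CPM in conventional T-like cells. Also higher in mregDC-like cells were Apol7c, Rrad, Pdcd1 (47.2 against 14.5 CPM, ratio 3.25 [1.72 to 6.65]) and the nuclear receptor gene Nr4a2 (481 against 227 CPM), while Ccl17, a chemokine that attracts T cells, was at 649 against 1181 CPM (ratio 0.549 [0.499 to 0.604]) and Eif3g, Rnf7 and Pik3cg were lower by size too. In this class 10 cells held 61.5% of the Hspa1a UMIs in CD94-KO and 80.6% in WT, and with each cell weighed the same its log2 difference went from 2.82 to 1.42. The Pdcd1 UMIs of the class lay in 17 CD94-KO and 9 WT cells.

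In cDC2-like cells, 211 in WT and 307 in CD94-KO, the protein C receptor gene Procr was at 75.5 against 22.2 CPM, the 4-1BB ligand gene Tnfsf9 at 70.5 against 31.0 CPM and Iqgap2 at 79.5 against 42.8 CPM, while the transcriptional inhibitor Id3 was at 42.6 against 97.8 CPM, Plin2 at 44.4 against 77.6 CPM, and AY036118 and Erdr1 were lower by size too. The log2 difference of Procr went from 1.57 to 0.34 with a mitochondrial limit of 5%, and that of Plin2 from -0.74 to -0.04 and of Tnfsf9 from 1.07 to 0.55 with the marker score. Some macrophage transcripts were higher in this class too, with C1qa at 52.1 against 14.5 CPM and C1qb at 76.6 against 25.6 CPM, while Lyz2 was at 1037 against 1316 CPM. Alternatively activated and tissue macrophage genes had a median of 0.38 [0.23 to 0.48] at percentile 100, 0.18 with each cell weighed the same, with Ccl22, Cd36 and Spp1 lower by size and 8 of 23 higher, 7 of which were below 0.25 of the level of the class where they were highest. Cd274 was at 823 against 450 CPM in neutrophil-like cells (ratio 1.83 [1.40 to 2.42]), at 192 against 101 CPM in Treg-like cells (ratio 1.9 [1.20 to 2.98]) and at 150 against 87.3 CPM in gamma-delta T-like cells (ratio 1.72 [1.19 to 2.54]), but close to level in cDC2-like (180 against 177 CPM) and mregDC-like cells (558 against 517 CPM). Free RNA was not tested as a source of the Treg-like and gamma-delta T-like counts. In Treg-like cells Gzmb was at 1413 against 2551 CPM (ratio 0.554 [0.483 to 0.633]) and Lag3 at 80.0 against 225 CPM (ratio 0.355 [0.192 to 0.612]), from 43 and 89 cells. Ccl24 transcripts, chosen after their values had been seen, were also higher in CD94-KO in classes other than monocyte/macrophage-like cells, with 779 against 91.2 CPM in neutrophil-like, 153 against 27.9 CPM in cDC2-like, 79.5 against 8.48 CPM in mregDC-like and 4.71 against 1.65 CPM in fibroblast-like cells. Nos2 (3.70 against 0.600 CPM) and S100a8 (3.03 against 0.750 CPM) were higher in fibroblast-like cells too, and whether these counts came from expression or from free RNA was not tested. Arg1 was at 1941 against 593 CPM in neutrophil-like cells but at 86.0 against 120 CPM in conventional T-like cells.

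The unnamed cluster led by AY036118 and Gm42418 held 26.1% of WT and 3.39% of CD94-KO cells, at a median of 646 and 698 UMIs. The median mitochondrial share was 0.502% [0.481 to 0.521] in its WT barcodes, against 1.71% in named WT immune cells. This argues against cells that lost cytoplasmic RNA but kept their mitochondria. It cannot speak to cells or nuclei that lost their mitochondria too, which would also have a low share. A larger variance ratio of marker counts of 2.0 [1.68 to 2.39] over a single common profile argues against free RNA of 1 pool as the whole source. That ratio was 1.48 for lymphoid markers, and named cells thinned to 646 UMIs gave 7.09 and 6.15. A first test of free RNA by joint detection of lymphoid and myeloid markers, at 0.999 [0.998 to 1.0] of the share expected by chance, decided nothing, since 99.9% of barcodes held myeloid markers, and the variance test replaced it for that reason, its prediction being written before its value was seen. A mixture of free RNA and cells of low RNA content may account for the cluster, and an effect of genotype cannot be separated from the library with 1 library per group.

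Klrd1 UMIs remained in the NK-like cells of the CD94-KO library at 0.478 of the WT level. Free RNA would reach every class alike, and the level was 24.7 [21.8 to 28.2] times that of the monocyte/macrophage-like cells of the same library, which argues against it as the source. A mixture of NK-like cells of unaltered mice with cells at the monocyte/macrophage-like Klrd1 level was calculated. At 3000 UMIs 49.0% [44.7 to 53.4] of 522 CD94-KO NK-like cells had no Klrd1 UMI, against 22.3% of 369 WT cells. That was below the 63.0% [59.5 to 66.5] of such a mixture and near the 45.5% of an even lowering in each cell. This argues against unaltered cells mixed with cells that lack the transcript. It cannot speak to a mixture with deficient cells that still make some transcript. The calculation of the mixture was refined after its first result had been seen, with the same outcome in each version. A transcript that is still made but carries the deletion may account for the pattern, and this was not tested, since the labels do not give the deleted part.

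Fibroblast-like cells were present after a CD45 sort, 184 in WT and 93 in CD94-KO. Ptprc, which encodes CD45, was at most 2.2% [1.64 to 2.87] of its level in named immune cells, in the CD94-KO library, which argues against doublets of stromal and immune cells. The Y-linked genes Ddx3y and Eif2s3y summed to 3.55% [1.98 to 5.86] of the immune level in CD94-KO and 1.98% in WT, which argues against stromal cells of the same mice, whose immune cells held them at 142 and 144 CPM. Tumour cells without a Y chromosome that passed the sort are a candidate source, which was not tested because the labels name no tumour line.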
